A study of Mus musculus with 2 samples.

How the data were processed

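RNA from the whole head of newborn mice was measured on 2 Affymetrix expression arrays, 1 for each of 2 genotypes. Both genotypes came from carriers of a reciprocal translocation between Chr 2 and Chr 9, named T11H, which can pass on offspring with both copies of a chromosome part from the same parent. In the head called MatDp(dist2) both copies of Chr 2 distal of the breakpoint were maternal and both copies of distal Chr 9 were paternal, per the labels. In the head called PatDp(dist2) the parental origins of both parts were the other way round. Imprinted genes, which are expressed from the copy of a given parent, can therefore be silent or doubly active in these parts. Per the labels' protocols, the tissue was snap frozen, total RNA was isolated on silica columns, and biotin-labelled cRNA was hybridised. The number of animals behind each sample and their sex are not given in the sources used here.

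The values used are the signals deposited by the authors, an intensity on a linear scale for each of 45101 probe sets per array. They came from MAS5 and GCOS, Affymetrix's software for summarising probes into a signal and for scaling arrays, per the submitters' processing notes, which give no versions. On each array the mean signal without the lowest and highest 2% of probe sets was 500.002, so the deposited values carry a scaling of each array to the same trimmed mean. MAS5 signals depend on mismatch probes and are noisy at low values. Detection calls were not used here, and a floor on the signal took their place. The floor was the median over both arrays of their 50th percentile, a signal of 187. No transformation other than log2 was applied to the deposited values.

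Probe sets were named through the platform annotation, with symbols updated by gene ID in a RefSeq gene table for GRCm38.p6. That table was used only for names, chromosomes and gene order, and no coordinates are printed because the values name no genome build. After 64 control probe sets were left out, 34945 probe sets had 1 gene symbol and 34741 of them had a gene ID in the RefSeq table. The 932 probe sets with several symbols and the 9211 that the annotation table did not list were left unnamed. Each of the 18193 genes was represented by its probe set with the highest mean log2 signal, except for imprinted genes of Chr 2 and Chr 9, for which every probe set is given.

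Each gene has a ratio of the MatDp(dist2) signal over the PatDp(dist2) signal. With 1 array per group there is no spread between replicates, no test and no p-value, and the number of arrays limits the precision of every value. The genome-wide counts took genes past a fixed 2-fold difference with both arrays at or above the floor. Where 1 array lay below the floor, the brighter signal over the floor is given as a bound ("at least N-fold"), and no fold is given where both arrays lay below it. Counts within gene lists, imprinted genes and chromosome parts also include genes whose bound reached 2-fold, and so follow a wider rule than the genome-wide counts. A gene is called measured where at least 1 array was at or above the floor. To describe a probe set against these arrays, the percentile of its log2 ratio among the 500 probe sets nearest in mean log2 signal is given. That percentile uses the deposited signals, also those below the floor, and not the bounds. A gene list of at least 3 measured members is described by its median log2 ratio, with bounds for members below the floor on 1 array, which can make the median understate the difference, and by the percentile of that median among 10000 random lists of the same size matched on mean log2 signal in 20 bins. The share of genes at least 2-fold apart on distal Chr 2 and on Chr 9 was placed among random lists in the same way. Distal Chr 2 stands here for the genes from H13 to the distal end, because the breakpoint is not placed by the labels, and for the same reason all of Chr 9 stands for its duplicated part and holds genes outside it.

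Before the data were examined, 28 gene lists were fixed. They cover imprinted genes of Chr 2, of Chr 9 and of other chromosomes by parental expression, and markers of neurons, glutamatergic and GABAergic neurons, astrocytes, oligodendrocytes and myelin, hypothalamus and pituitary, skeletal muscle, cartilage, bone and tooth, epidermis and hair, oral and nasal epithelium, eye lens and retina, red and white blood cells, endothelium, fat and liver-made plasma proteins. The others hold genes of the cAMP response, immediate early response, hypoxia and glycolysis, cell cycle, cytosolic ribosome, oxidative phosphorylation, glucocorticoid and stress response, and sex-linked genes. Of 492 list entries, 437 were found on the arrays. The rule for named genes was also fixed. It took every probe set of the imprinted lists of Chr 2 and Chr 9, the 10 highest and 10 lowest ratios measured on both arrays, up to 5 genes each way with a bound and a signal of at least 4 times the floor, the 3 members of each list with the largest absolute log2 ratio, and the 3 highest and 3 lowest genes of distal Chr 2 and of Chr 9. Other genes named in the text were chosen after their values were seen, and so were 11 further gene lists, used mainly in the closing section.

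The alternatives tried were median centring of the log2 ratios, quantile normalization, a loess fit of the log2 ratio on mean log2 signal with a span of 0.3, floors at the 30th and 70th percentiles, an offset of 100 added to each signal, the mean over probe sets of a gene, and fold thresholds of 1.5 and 3. That mean took only probe sets with both arrays at or above the floor, and genes without such a probe set kept the one of highest mean signal. The counting was tested on simulated arrays of the same 18193 genes with a noise SD of 0.3 on the log2 scale. It found 50 of 50 genes changed by a log2 ratio of 3 and 47 of 50 changed by 1.5, in each direction, and 6 of 11445 unchanged genes passed 2-fold. The changed genes were drawn only from bright genes with a mean signal far above the floor, so their recovery does not describe dim genes. The measured log2 ratios had a wider robust SD, from 0.32 among bright to 0.45 among dim probe sets, and with a noise SD of 0.45 in the simulation 277 of 11296 unchanged genes passed 2-fold. Of 200 simulated lists of unchanged genes, 5 lay outside the central 95% of random lists. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.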

Results

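Heads of newborn mice with a maternal duplication of distal Chr 2, MatDp(dist2), and with a paternal duplication, PatDp(dist2), were compared on 1 array each. The comparison asks which transcripts differ when both copies of a chromosome part come from the mother or from the father, and so which genes of the part depend on parental origin. The reciprocal part of Chr 9 was paternal in the MatDp(dist2) head and maternal in the PatDp(dist2) head. Signals ranged from 0.1 to 22236 in the MatDp(dist2) head and from 0.1 to 22894.5 in the PatDp(dist2) head, with medians of 201 and 173. At or above the floor of 187 were 51.6% of probe sets in the MatDp(dist2) head and 48.3% in the PatDp(dist2) head. Each value below is from 1 array, without replicates, so no difference was set against the spread between animals.

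Several imprinted genes of distal Chr 2 differed between the heads, and the ratio of Nnat, as a bound, was the lowest of all measured genes. Nnat, a paternally expressed gene for a small membrane protein of the developing brain, had a signal of 3927 in the PatDp(dist2) head and of 43.1, below the floor, in the MatDp(dist2) head, which makes it at least 21.0-fold higher with the paternal duplication. Mcts2, a paternally expressed retrogene inside an intron of H13, was at least 3.85-fold higher in the PatDp(dist2) head, with signals of 720.4 and 90.4, while its X-linked paralog Mcts1 had 3058 and 2431. Blcap, whose intron contains Nnat, went the other way and was 2.41-fold higher in the MatDp(dist2) head, with signals of 2397 and 993. On Chr 9, Rasgrf1, a paternally expressed exchange factor for Ras, was at least 3.44-fold higher in the MatDp(dist2) head, which carried the paternal duplication of distal Chr 9. Neuron markers as a group were also higher in the MatDp(dist2) head, with a median of 2.02-fold.

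H13, which encodes signal peptide peptidase, gave probe sets of both directions. Probe set 1417287_at had signals of 1172 in the MatDp(dist2) head and 247 in the PatDp(dist2) head, a 4.74-fold difference. Probe set 1438456_at was at least 3.68-fold higher in the MatDp(dist2) head, with signals of 688 and 179, and 1438865_at was at least 1.60-fold higher there. Probe set 1455631_at was at least 2.14-fold higher in the PatDp(dist2) head, with signals of 401 against 96.1. The other 2 of the 6 H13 probe sets, 1428855_at and 1428856_at, lay below the floor on both arrays.

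Gnas, which encodes the stimulatory G protein subunit and several imprinted transcripts, differed strongly on 1 of its 5 probe sets. Probe set 1427789_s_at had a signal of 498 in the MatDp(dist2) head and 4.7 in the PatDp(dist2) head, at least a 2.66-fold difference. The brightest Gnas probe set, 1450186_s_at, had signals of 13786.5 and 14948, and 1453413_at had 202 and 218, while 1443375_at and 1421740_at lay below the floor on both arrays. Which Gnas or H13 transcript each probe set reads was not analysed here. The probe set for Nespas, the antisense transcript of the Gnas locus, lay below the floor in both heads, with signals of 62.3 and 49.6. Ntm, a cell adhesion gene of Chr 9, was higher in the MatDp(dist2) head by 1.69-fold, 1.88-fold and 2.05-fold on its 3 probe sets. Besides 1435614_s_at, with signals of 643 in the MatDp(dist2) head and 136 in the PatDp(dist2) head, Rasgrf1 had a probe set at 262 and 3.3, and another below the floor on both arrays.

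The remaining members of the imprinted lists differed less. Sfmbt2, a proximal Chr 2 gene of the Polycomb group, was at least 1.65-fold higher in the MatDp(dist2) head on 1 probe set and below the floor on the other. Sgk2, a kinase gene, had signals of 199 and 179, Gatm, an enzyme of creatine synthesis, had 1459 and 1493, and Wt1 lay below the floor in both heads. Of 12 listed genes on the arrays 10 were measured, and 7 had a probe set at least 2-fold apart, with 6 such probe sets higher in the MatDp(dist2) head and 3 higher in the PatDp(dist2) head. Among the 500 probe sets nearest in mean signal, the log2 ratio of Nnat lay at percentile 0.0, Mcts2 at 0.0, H13 1455631_at at 0.6, H13 1417287_at at 99.0, Blcap at 98.2, Gnas 1427789_s_at at 99.8 and Rasgrf1 1435614_s_at at 99.6. Apart from H13 1417287_at and Blcap, each of these ranks used 1 signal below the floor, where only a bound is given otherwise. The neighbours of Gnas 1427789_s_at were noisy, with a robust SD of 0.86 against 0.44 for those of Nnat. The median log2 ratio of the 8 measured Chr 2 genes was 0.03, at percentile 53.3 of random matched lists, with a mean of -0.27 of the opposite sign, because Nnat and Mcts2 lay opposite to H13 and Blcap. The count of 7 genes was 3 with the higher floor, at the 70th percentile, where Blcap, H13 and Nnat were left, and 4 at a 3-fold threshold, where H13, Mcts2, Nnat and Rasgrf1 were left. Ntm was under 2-fold with median centring, quantile normalization, the loess fit, the offset of 100 and the mean over probe sets. Gnas was under it with that mean, which left out 1427789_s_at because its PatDp(dist2) signal lay below the floor. For H13 the mean rested on 1417287_at alone for the same reason.

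**Figure D1:**
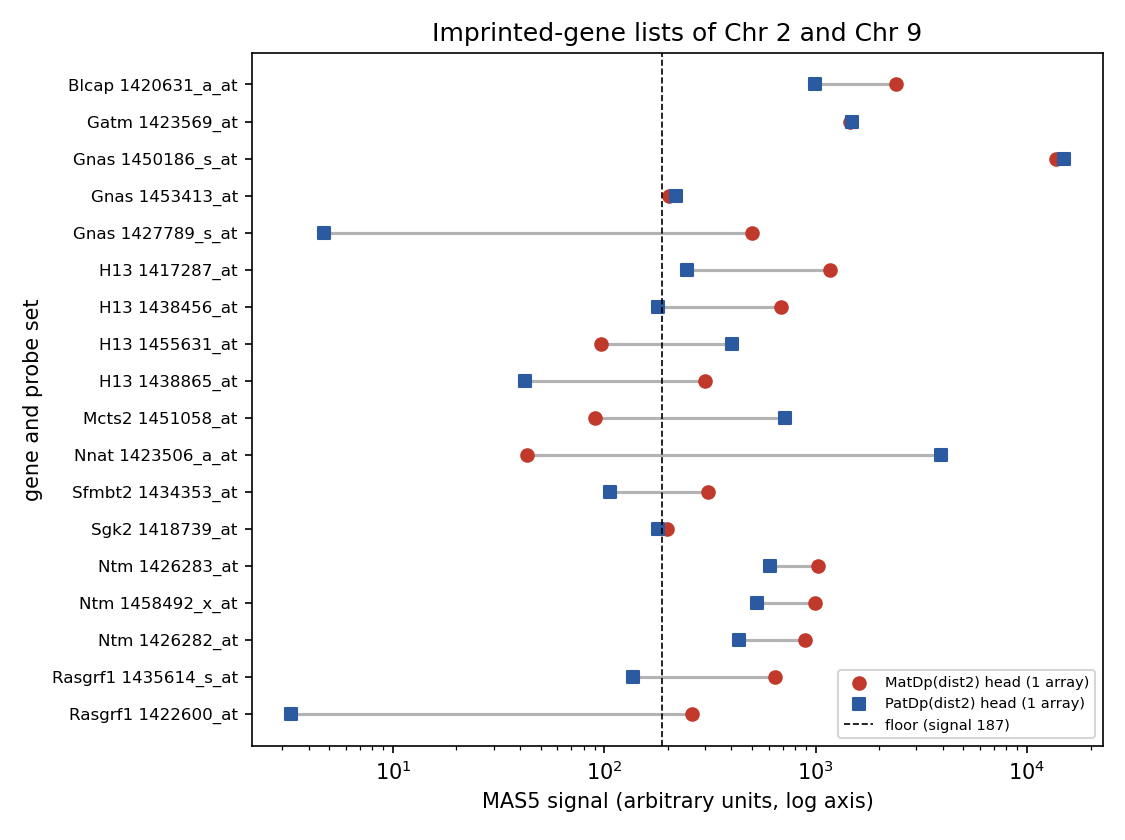
Signal (arbitrary units, log axis) of each measured probe set of the imprinted-gene lists of Chr 2 and Chr 9, with a circle for the MatDp(dist2) head and a square for the PatDp(dist2) head, 1 array each, and a dashed line at the floor of 187. Nnat and Mcts2 lay far to the right in the PatDp(dist2) head, and Blcap, Rasgrf1 and most H13 probe sets in the MatDp(dist2) head.

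Imprinted genes of other chromosomes, whose parental origin did not differ between the heads, lay closer together. They are counted on 1 probe set per gene, while the count for Chr 2 and Chr 9 above took any probe set. On 1 probe set per gene, 2 of 8 measured Chr 2 genes were at least 2-fold higher in the MatDp(dist2) head and 2 in the PatDp(dist2) head. These 8 include Sfmbt2 and Gatm, which lie proximal of H13 and so outside the part that stands here for distal Chr 2. Of 2 Chr 9 genes, 1 was at least 2-fold higher in the MatDp(dist2) head. Several genes compared here, such as Igf2 and Meg3, were very bright, where ratios spread less. Of 16 measured paternally expressed genes 0 were at least 2-fold apart, and their median log2 ratio was -0.08, at percentile 51.7 of random matched lists. The largest differences among them were those of Usp29 (signals 471 in MatDp(dist2) and 252 in PatDp(dist2)), Inpp5f, a phosphoinositide phosphatase (3469 and 2372), and Slc38a4, an amino acid transporter (700.2 and 953). Of 18 measured maternally expressed genes 0 were at least 2-fold apart, with a median of -0.15 at percentile 23.0. Mirg, a noncoding RNA with signals of 2489.8 and 3599, Klf14, with 404 and 552, and Commd1, with 879 and 1161, differed the most.

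Across the genome, the genes with large folds included lens crystallins and barrier genes of the epidermis, which were higher in the MatDp(dist2) head, and muscle and lipid genes, which were higher in the PatDp(dist2) head. Ttr, the thyroxine carrier of plasma and choroid plexus, was 39.6-fold higher in the MatDp(dist2) head, with signals of 12952 and 327. The barrier genes of the outer epidermis Lor (20.5-fold), Krt10 (17.2-fold), Krt1 (16.2-fold), Lce1b (11.7-fold), Lce1h (8.57-fold) and Krtdap (8.29-fold) were also among the 10 highest measured on both arrays, together with the calmodulin-like gene Calm4 (15.8-fold), the protease inhibitor Stfa3 (21.0-fold) and the salivary gene Dcpp1 (17.0-fold). The lens crystallins Cryba1, Cryga, Crybb1 and Crygb had signals of 9053, 6741, 6472 and 4640.4 in the MatDp(dist2) head and lay below the floor in the PatDp(dist2) head, for bounds of 48.4-fold, 36.0-fold, 34.6-fold and 24.8-fold. Flg, the precursor of filaggrin in the cornified layer, had a signal of 4959 against 49.9, at least 26.5-fold.

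Among genes at or above the floor on both arrays, the highest ratio in the PatDp(dist2) head was that of Mb, the oxygen-binding myoglobin of muscle, with a signal of 2983 against 224, 13.3-fold. The fast myosin gene Myh2 (7.02-fold) and Pdk4 (6.80-fold), a kinase that restrains glucose oxidation, were also higher there. Car6, a carbonic anhydrase secreted in saliva, was 11.0-fold higher, Prol1, a lacrimal gland gene, 8.65-fold and the mucosal gene Dmbt1 7.14-fold. The lipid genes Ces1d (7.26-fold), Plin4 (6.64-fold) and Scd1 (6.53-fold), together with Mrap (6.99-fold), completed the 10 genes with the largest folds in that direction among those measured on both arrays. Besides Nnat, the secretory genes Mucl2, Scgb2b27 and Prpmp5 were at least 7.92-fold, 6.45-fold and 5.43-fold higher, and Pparg, the master regulator of fat cells, at least 4.62-fold, with their MatDp(dist2) signals below the floor.

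Of 11270 genes at or above the floor on both arrays, 420 were at least 2-fold higher in the MatDp(dist2) head, 397 were at least 2-fold higher in the PatDp(dist2) head, and 10453, or 92.8%, were less than 2-fold apart. In simulated arrays, 277 of 11296 unchanged genes lay past 2-fold in either direction at a noise SD of 0.45, the robust SD of the log2 ratio among dim probe sets here. That count does not estimate how many of the measured differences are noise. The simulated noise was normal, and 1 array per genotype cannot separate noise from differences between the heads. A further 133 genes had a bound of at least 2-fold higher in the MatDp(dist2) head and 36 in the PatDp(dist2) head. Over the 20811 probe sets at or above the floor on both arrays, the log2 ratio had a median of 0.04 and an SD of 0.54, and the log2 signals had a Pearson correlation of 0.927 across probe sets, which are not independent replicates. The median log2 ratio went from 0.14 among probe sets with a mean log2 signal of 8 to 9 to -0.15 among those of 12 to 15. The count of genes higher in the MatDp(dist2) head was 681 with the lower floor, at the 30th percentile, 169 with the floor at the 70th percentile and 278 with an offset of 100.

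**Figure D2:**
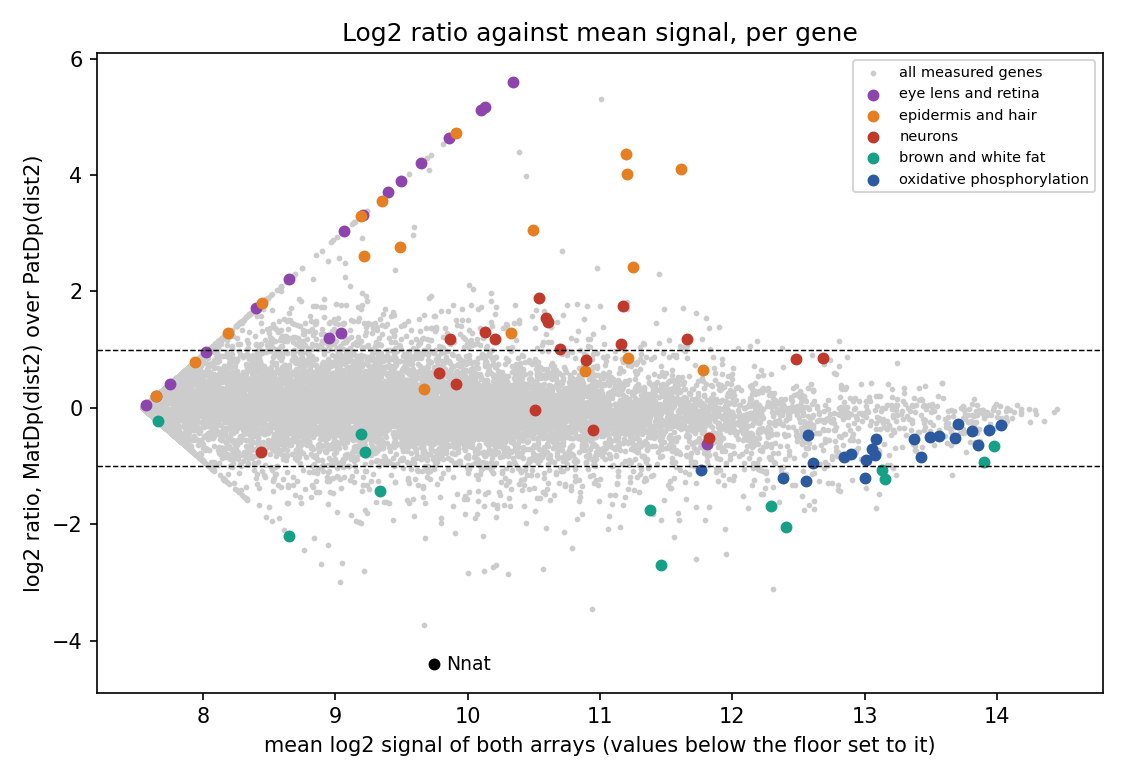
Log2 ratio of the MatDp(dist2) over the PatDp(dist2) signal (vertical axis) against the mean log2 signal of both arrays (horizontal axis), 1 point per measured gene, with values below the floor set to it and dashed lines at 2-fold. Cryga lay at 5.17 and Flg at 4.73, and 13 of 18 eye genes and 13 of 19 epidermis genes were at least 2-fold higher in the MatDp(dist2) head, while fat and oxidative phosphorylation genes lay below 0, and Nnat lay at -4.39.

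Markers of neurons and of the lens and skin were higher in the MatDp(dist2) head as groups. Of 19 measured neuron genes, 10 were at least 2-fold higher in the MatDp(dist2) head and 0 in the PatDp(dist2) head, with a median of 2.02-fold. The neuronal tubulin Tubb3 (signals 2853 and 775), Dcx, a microtubule protein of migrating neurons (4241 and 1259), and the RNA-binding protein gene Elavl3 (2634 and 908) differed the most. The other direction was taken by 4 of the 19, Camk2a (268 and 451.5), Nefl (3037 and 4339), Nefm (1735 and 2259) and Thy1 (1438 and 1473). Of 15 measured genes of glutamatergic and GABAergic neurons, 9 were at least 2-fold higher in the MatDp(dist2) head and 0 in the PatDp(dist2) head, with a median of at least 2.17-fold. Neurod6, a transcription factor of cortical excitatory neurons, had signals of 2752 and 90.1, Neurod2 had 1184 and 206, and Gad1, the enzyme that makes GABA, had 2420.5 and 709.

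Of 18 measured eye genes, 13 were at least 2-fold higher in the MatDp(dist2) head and 0 in the PatDp(dist2) head, with a median of at least 6.17-fold. Cryab, a crystallin also made in muscle, was the exception to the direction of the list, with signals of 2887 and 4443. The pigment cell genes Pmel (828 and 337.5) and Dct (748 and 327) were higher in the MatDp(dist2) head. Of 19 measured genes of epidermis and hair, 13 were at least 2-fold higher in the MatDp(dist2) head and 0 in the PatDp(dist2) head, with a median of at least 5.37-fold, and Flg, Lor and Krt10 had the largest differences. The medians of these 4 lists, neurons, transmitter-defined neurons, eye and epidermis, lay at percentile 100 of random matched lists under the deposited scaling and each of the 7 alternatives of scaling, floor, offset and probe set choice.

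Cartilage genes were higher in the MatDp(dist2) head too, with 4 of 12 measured genes at least 2-fold higher, 0 at least 2-fold lower, and a median log2 ratio of 0.38 at percentile 99.5. Col2a1, the main collagen of cartilage, had signals of 2660.5 and 1159, Sox5, a regulator of cartilage cells, had 402 and 83.7, and Cnmd, the cartilage protein chondromodulin, had 399 and 163.

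Fat, muscle and mitochondrial genes were higher in the PatDp(dist2) head. Of 13 measured genes of brown and white fat, 8 were at least 2-fold higher in the PatDp(dist2) head and 0 in the MatDp(dist2) head, with a median of 2.34-fold at percentile 0 of random matched lists. Scd1, a fatty acid desaturase, had signals of 1106 in MatDp(dist2) and 7217 in PatDp(dist2), and Cidea, a lipid droplet protein of brown fat, had 2677 and 11022. All 25 measured skeletal muscle genes had a higher signal in the PatDp(dist2) head, 4 of them at least 2-fold, with a median log2 ratio of -0.56 at percentile 0.02. Random matched lists themselves had a median of -0.17, so the direction of a single bright gene says little. Mb, the fast myosin Myh1 (1912 and 8138) and the slow myosin Myh7 (1103.5 and 2808) differed the most. In the same direction, 6 Hox genes of neck and trunk, a list chosen after the data were seen, had a median log2 ratio of -0.49 at percentile 0.32.

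All 22 measured oxidative phosphorylation genes were likewise higher in signal in the PatDp(dist2) head, 4 of them at least 2-fold, with a median of 1.59-fold at percentile 0 of random matched lists. On the log2 scale that median was -0.67, against -0.20 for the random matched lists, which also lay below 0. Sdha of complex II had signals of 3892 in MatDp(dist2) and 9326 in PatDp(dist2), Uqcrc2 of complex III had 5421 and 12459, and Ndufv1 of complex I had 3531 and 8095. Of 17 measured genes of hypoxia and glycolysis, 3 were at least 2-fold higher in the PatDp(dist2) head and 0 in the MatDp(dist2) head, with a median log2 ratio of -0.48 at percentile 0.25, which the loess fit moved inside the central 95% (percentile 2.925). The glucose-phosphorylating enzyme Hk2 (1193 and 2834), the mitophagy gene Bnip3 (2747 and 6199.8) and Higd1a (3313 and 6708) had the largest differences.

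White blood cell, vessel and myelin genes were higher in the PatDp(dist2) head as lists, by smaller folds. All 13 measured white blood cell genes had a higher signal there, 2 of them at least 2-fold, with a median log2 ratio of -0.50 at percentile 0.04, led by the neutrophil proteins S100a8 (448 and 1320.2), S100a9 (312 and 666) and Ltf (617 and 1062). Of 14 measured endothelial and pericyte genes, 13 had a higher signal there and 2 were at least 2-fold higher, with a median of -0.54 at percentile 0.01. These 2 were the receptors Flt1 (333 and 766) and Tek (568 and 1195), and the receptor Kdr followed (1105.5 and 1813.5). Of 9 measured genes of the oligodendrocyte lineage and myelin, 2 were at least 2-fold higher in the PatDp(dist2) head, Mbp (1119.8 and 4621) and Cnp (1083 and 2278), and the median of -0.45 lay at percentile 0.69. With the floor at the 30th percentile or the mean over the probe sets of a gene, the myelin list lay inside the central 95%, at most at percentile 5.87. Mag, a myelin adhesion protein, had signals of 205 and 330.4. In this list 6 genes had a higher signal in the PatDp(dist2) head and 3 in the MatDp(dist2) head. These 3 were the lineage genes Pdgfra (3588 and 3459), Olig1 (831 and 751) and Olig2 (187.5 and 90.4). Probe sets of Mbp disagreed, since 1 of them had signals of 586 and 382.5, the other way round from the brightest.

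The cAMP response list, which bears on signalling through Gnas, lay at a median log2 ratio of -0.32 and percentile 0.61, but its 14 measured members were mixed. Nr4a3, an orphan nuclear receptor, was at least 2.76-fold higher in the MatDp(dist2) head and Pde10a, a phosphodiesterase of the striatum, 2.31-fold higher there, while Ppargc1a, a coactivator of mitochondrial genes that the fat list also holds, was 2.71-fold higher in the PatDp(dist2) head. The other 11 members were less than 2-fold apart.

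The other lists lay inside the central 95% of random matched lists under the deposited scaling. Bone and tooth lay below it in 3 of 8 settings (quantile normalization, the loess fit and the mean over probe sets, down to percentile 0.57), and oral and nasal epithelium in 2 of 8 (quantile normalization and the loess fit, down to 0.39). With the floor at the 70th percentile, cell cycle (98.75) and hypothalamus and pituitary (99.6) lay above it. Astrocyte and radial glia genes had a median of 0.19 at percentile 95.2 and a mean of -0.01, with S100b (511 and 1292), Aqp4 (737.5 and 1621), the water channel of astrocyte endfeet, and Glul (3197 and 6508), glutamine synthetase, at least 2-fold higher in the PatDp(dist2) head. Bone and tooth genes had a median of -0.31 at percentile 3.68, with 3 of 14 measured genes at least 2-fold higher in the PatDp(dist2) head, the enamel and dentin genes Ambn (1523.5 and 4128), Dspp (489 and 1153) and Amelx (2619 and 5834). Oral and nasal epithelium genes split, with the keratins Krt13 (4420.2 and 1260.4), Krt6a (4096 and 1896) and Krt4 (7551 and 3721) at least 2-fold higher in the MatDp(dist2) head and the mucin Muc5b (359.8 and 847) in the PatDp(dist2) head, and a median of -0.30 at percentile 4.59.

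Hypothalamus and pituitary genes had 5 measured members and a median of 0.24 at percentile 85.5, with growth hormone, Gh, at 2146 and 519, the stress hormone precursor Pomc at 368 and 683, and oxytocin, Oxt, at 1450.1 and 805. Red blood cell genes had a median of -0.20 at percentile 21.8, with the embryonic globin Hbb-y at 453 and 13.1, the anion exchanger Slc4a1 at 413 and 775.5, and the transferrin receptor gene Tfrc at 2558 and 4066. Cell cycle genes had a median of 0.19 at percentile 96.1 with 0 of 18 measured genes at least 2-fold apart, and Aurkb, Pcna and Top2a differed the most, by 1.33-fold, 1.30-fold and 1.28-fold. Genes of the glucocorticoid and stress response, at a median of -0.22 and percentile 3.32, immediate early genes, at -0.22 and 6.55, and cytosolic ribosomal protein genes, at -0.07 and 81.7, also had 0 members at least 2-fold apart. The metallothionein Mt1 (2350.3 and 4635), Zbtb16 (949.6 and 1687) and Lcn2 (272.5 and 407) led the stress list, Fos (816 and 1148), Ier2 (545 and 408) and Egr2 (167.5 and 237) the immediate early list, and Rpl27a (1099 and 1934), Rps6 (639 and 511) and Rpl7 (13042 and 15420.5) the ribosomal list.

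Y-linked transcripts had like signals in both heads, with Eif2s3y at 1169 and 1365, Uty at 485.5 and 619 and Kdm5d at 472 and 489. Xist, the noncoding RNA of the inactive X, had signals of 217 and 202 on 1 probe set and lay below the floor on the other 2, and the sex-linked list had a median of -0.14 at percentile 20.8. Of the liver-made plasma proteins only Ttr and Apoh, with signals of 242 and 125, were measured, so that list was not placed. The list of imprinted Chr 9 genes, Rasgrf1 and Ntm, was not placed either. In all, 13 of 26 placed lists lay outside the central 95% of random matched lists, 5 of them higher in the MatDp(dist2) head and 8 higher in the PatDp(dist2) head, against 1.3 expected by chance. The lists share some genes and tissues and are not independent of each other. The 1.3 holds for randomly drawn genes, while genes of 1 tissue can rise or fall together with its share of a sample.

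**Figure D3:**
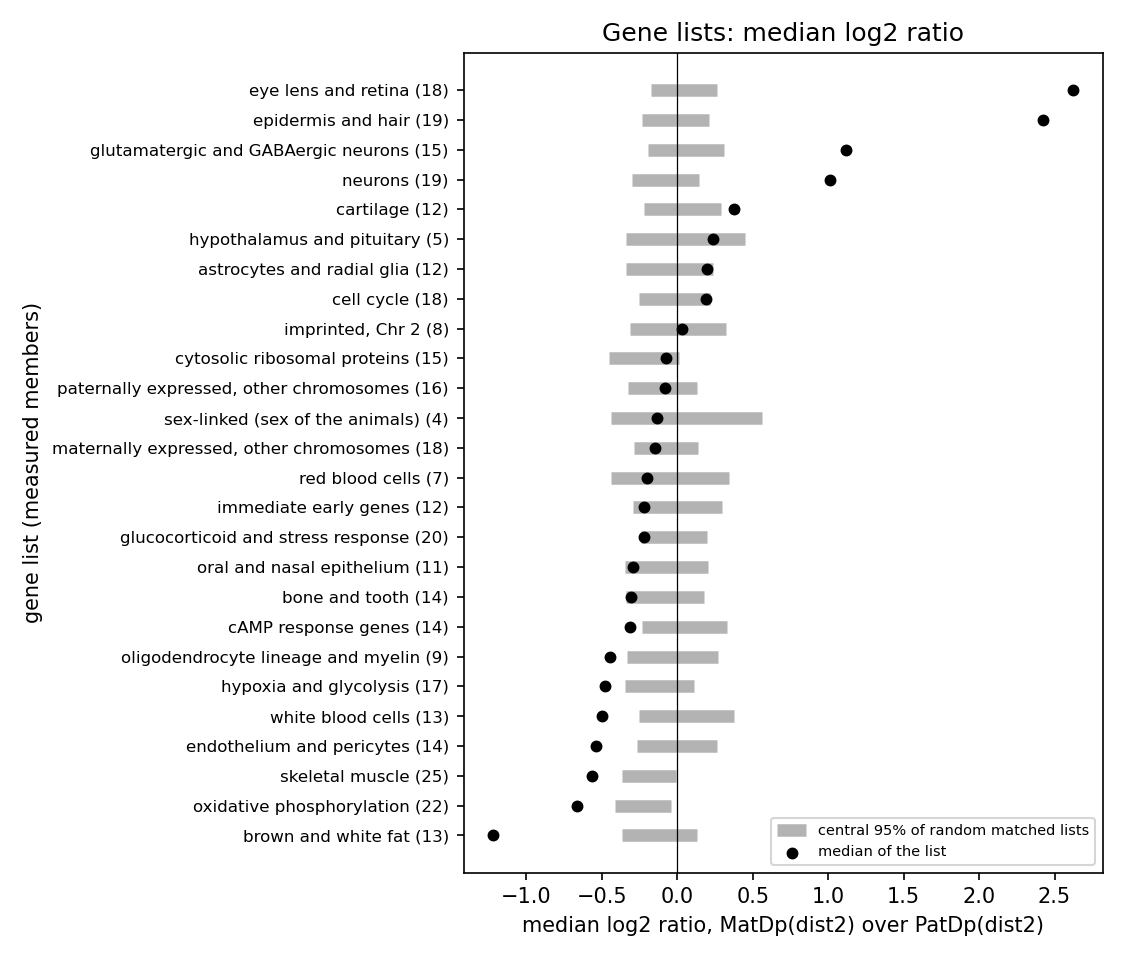
Median log2 ratio of the MatDp(dist2) over the PatDp(dist2) signal for each placed gene list (points, 1 array per group, number of measured members in brackets) beside the central 95% of random lists matched on signal (bars). Eye, epidermis, both neuron lists and cartilage lay above their bars, and fat, oxidative phosphorylation, muscle, vessels, white blood cells, hypoxia and glycolysis, myelin and the cAMP response lay below theirs.

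Distal Chr 2 and Chr 9 did not stand apart from random genes of like signal in their share of 2-fold differences. On distal Chr 2, from H13 to the distal end, 22 of 242 measured genes were at least 2-fold apart, 12 higher in the MatDp(dist2) head and 10 higher in the PatDp(dist2) head. That share of 9.09% lay at percentile 75.3 of random matched lists, whose central 95% ran from 4.55% to 11.6%. The median log2 ratio of these genes was 0.07, at percentile 95.2. Slpi, a protease inhibitor of mucosal secretions, was 7.58-fold higher in the MatDp(dist2) head, with signals of 1625 and 214, followed by H13 and by Bpifb9b, of a secretory protein family (3.40-fold). Adig, a gene of fat cell differentiation, was 5.10-fold higher in the PatDp(dist2) head, Bpifa2, a salivary protein, 3.31-fold and Acss2, an acetyl-CoA synthetase, 3.28-fold. Vstm2l, a gene near Blcap and Nnat chosen after its value was seen, had signals of 1979 and 767, a direction that it shared with Blcap.

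On Chr 9, taken whole because the breakpoint is not placed by the labels, 52 of 704 measured genes were at least 2-fold apart, 30 higher in the MatDp(dist2) head and 22 higher in the PatDp(dist2) head. The share of 7.39% lay at percentile 26.3 of random matched lists, and the median log2 ratio of -0.01 at percentile 4.0. The neuronal genes Celsr3, a cadherin of axon guidance (3.64-fold), Plppr2 (3.31-fold) and Camkv (2.98-fold) had the highest ratios measured on both arrays in the MatDp(dist2) head. Myl3, a slow muscle myosin light chain (3.91-fold), Slc25a20, the mitochondrial carnitine carrier (3.54-fold), and Tmem45b (2.72-fold) had the highest in the PatDp(dist2) head. Markers of neurons were higher in the MatDp(dist2) head and those of muscle in the PatDp(dist2) head over the whole genome, as given above. At a 3-fold threshold the share on distal Chr 2 was 4.13%, at percentile 97.4, and that on Chr 9 was 0.994%, at percentile 1.82. By chromosome, the share of genes at least 2-fold apart ran from 4.83% on Chr 8 to 11.7% on Chr 3, with Chr 9 at rank 14 and all of Chr 2, at 7.11%, at rank 17 of 20.

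**Figure D4:**
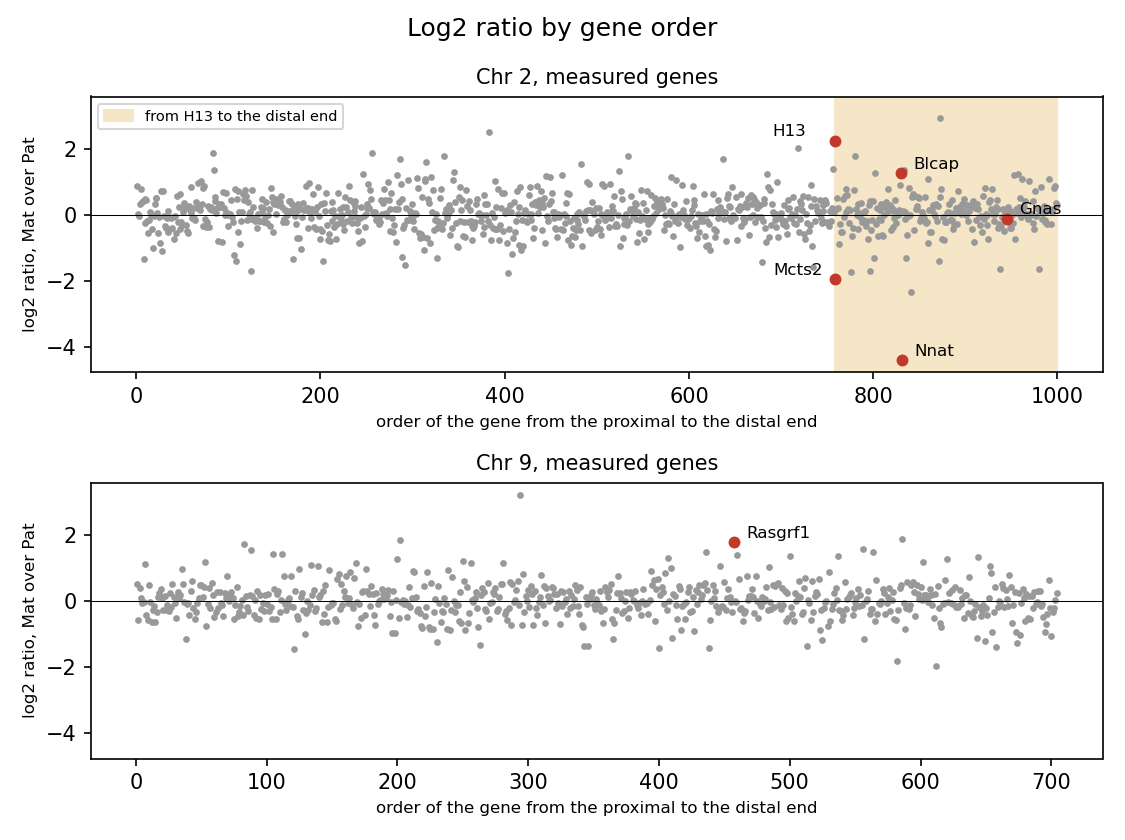
Log2 ratio of the MatDp(dist2) over the PatDp(dist2) signal for each measured gene of Chr 2 and Chr 9 (vertical axes) by gene order from the proximal to the distal end (horizontal axes), 1 array per group, with the part from H13 to the distal end of Chr 2 shaded. Nnat and Mcts2 lay below 0 and H13 and Blcap above it, and Rasgrf1 lay above most genes of Chr 9.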

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

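Each alternative was fixed before the data were examined. No paired analysis was possible because each group holds 1 array, and for the same reason no array could be left out. The number of genes at least 2-fold higher in MatDp(dist2) was 420, against 681 with the floor at the 30th percentile, 169 with the floor at the 70th percentile and 278 with an offset of 100. It was 1225 at a 1.5-fold and 84 at a 3-fold threshold. The number higher in PatDp(dist2) was 397, against 1258 at 1.5-fold and 93 at 3-fold. The imprinted genes at least 2-fold apart numbered 7, against 3 with the floor at the 70th percentile and 4 at 3-fold, and 5 to 8 under the others. The share of distal Chr 2 genes was 9.09%, against 7.02% with the offset, 20.7% at 1.5-fold, 4.13% at 3-fold and 7.11% over all of Chr 2. The share of Chr 9 genes was 7.39%, against 8.52% and 6.09% with the floor at the 30th and 70th percentiles, 5.26% with the offset, 20.9% at 1.5-fold, where it lay at percentile 4.24, and 0.994% at 3-fold. The floor and the threshold set how many genes can pass, by construction, and an offset shrinks the ratios of dim genes. The share of 2-fold calls that were higher in MatDp(dist2) was 51.4%, 57.3% with the floor at the 30th percentile and 38.5% at the 70th, and 47.0% to 48.9% under the 3 other scalings. Those scalings moved the median log2 ratio of genes with both arrays at or above the floor by less than 0.1. Between 12 and 15 lists lay outside the central 95%. Of the values of named genes, 732 moved by less than the spread of probe sets of like signal and 77 by more, and of the list medians 152 by less than the SD of random lists and 30 by more, with no called value changing sign. Signals near the floor limit the comparison, since 5710 genes lay below it on both arrays and have no fold.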

Other observations

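The tests of pattern causes were chosen after the results were seen, apart from the test of the H13 probe sets, and the gene lists in these paragraphs were also chosen after the data were seen. Several of these lists hold genes already picked for their ratios (such as crystallins, Lor, Krt10, Mb, Car6 and Prol1), so their medians and percentiles describe these genes and test nothing.

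Within tissues, subsets of genes differed in size or direction. The 14 lens fibre genes had a median of at least 11.4-fold higher in the MatDp(dist2) head, with each of them below the floor in the PatDp(dist2) head. Of 15 genes of differentiated epidermis 13 were at least 2-fold higher in the MatDp(dist2) head, with a median of at least 8.29-fold, while 0 of 9 genes of basal epidermis were, with Krt5 at signals of 4407 and 2796 and Krt14 at 2359 and 1517. Of 12 forebrain genes 8 were at least 2-fold higher in the MatDp(dist2) head, with a median log2 ratio of at least 1.15 at percentile 100 of random matched lists, and Lhx2, a regulator of cortex and eye, had signals of 924 and 253. Of a midbrain and hindbrain list 6 genes were measured, with a median of -0.57 at percentile 0.22. The members below 0 were mainly the Hox genes Hoxb2 (-0.79), Hoxb3 (-0.64) and Hoxa3 (-0.51) and the glycine transporter Slc6a5 (-0.70), while Pax7 lay at -0.07 and Zic1, a cerebellar gene, at 1.39, so the list does not speak for midbrain and hindbrain as a whole. Of 12 mature muscle genes 8 were at least 2-fold higher in the PatDp(dist2) head, with a median of -1.27 at percentile 0, while 0 of 10 immature muscle genes were, with a median of -0.33 at percentile 7.41. Embryonic myosin, Myh3, had signals of 9164.5 and 11874, and perinatal myosin, Myh8, had 15467 and 18832. Each had a signal above 10000, as did mature genes such as Ckm, and log2 ratios of probe sets that bright spread less. The robust SD was 0.24 near Myh3 and 0.20 near Myh8.

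Salivary and lacrimal gland genes were mostly higher in the PatDp(dist2) head, with 8 of 14 measured genes at least 2-fold higher there and a median of 2.79-fold at percentile 0, on a list that includes Car6, Prol1, Dmbt1, Prpmp5 and Bpifa2, genes already named for their ratios. The kallikrein Klk1 had signals of 466 and 3025, and Pip, a secreted gland protein, had 1660.1 and 9439. Dcpp1 alone was at least 2-fold higher in the MatDp(dist2) head, while its paralog Dcpp3 had signals of 1920 and 3389.5. Choroid plexus genes had a median of 0.43 at percentile 94.7, and only Ttr of 7 measured genes was at least 2-fold apart, with Clic6 at 616 and 456 and Sostdc1 at 1820 and 1497. Otx2 (316 and 26.0) and Kcnj13 (261 and 132) went with Ttr, with bounds of 1.69-fold and 1.40-fold. All 4 Ttr probe sets had the same direction, the dimmest with signals of 5371 and 30.1. The 10 measured genes of peripheral ganglia and Schwann cells had a median of -0.28 at percentile 3.57.

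Lens, differentiated epidermis and forebrain genes were lower in the PatDp(dist2) head. More degraded RNA in either sample was argued against, since the 3' over 5' signal ratios of Actb and Gapdh differed by at most 1.11-fold between the arrays. A smaller share of lens in the PatDp(dist2) sample stays open, because the 14 of 14 lens fibre genes that lay below the floor there restate the pattern and do not test it. For the epidermis a smaller share stays open too, because the basal genes, which oral and gland epithelia also make, had a median log2 ratio of only 0.25 at percentile 93.8. An effect of the genotype could not be separated from a difference in dissection, with 1 array per genotype.

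Mature muscle and mitochondrial genes were higher in the PatDp(dist2) head. More muscle stays open. The gap of 1.49 between the median log2 ratios of 7 immature (-0.43) and 9 mature genes (-1.92), all with signals under 10000, rests on genes named for their ratios. Without Mb and Myh2 the gap was 0.89 over 7 mature genes, against 0.54 for 2 SD of random lists. Myh1 was also named for its ratio, and Cox7a1, Cox8b and Ncam1 are made by other tissues. Without these as well, a gap of 0.68 barely exceeded the 0.64 of 2 SD, on 4 mature genes. A minimum of 5 mature genes, set after these values were seen, was asked for. An older animal behind the PatDp(dist2) sample stays open too. The embryonic globin Hbb-y was lower there (a bound of 1.28 on the log2 scale, or at least 2.42-fold). On the other side, differentiated epidermis genes (median 3.05) were lower there as well. Of 10 immature muscle genes 9 were higher in signal there, but the list median of -0.33 lay at percentile 7.41 of random matched lists. Those random lists had a median of -0.12 and ran from -0.43 to 0.15. The immature muscle genes therefore cannot decide the question of age. More neck tissue in the PatDp(dist2) sample may account for part of the pattern. The 6 Hox genes of neck and trunk had a median of -0.49 at percentile 0.32. The genotype also stays open as untested, and the labels give both samples as newborn whole heads.

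Imprinted genes of Chr 2 and Chr 9 differed between heads whose tissue content also differed. For Nnat, neuron content was argued against, since its log2 ratio of -4.39 (a bound) lay below the range of the neuron list, -0.75 to 1.88. That ratio was the lowest of 12483 measured genes. Muscle and gland genes were mostly higher in the PatDp(dist2) head. The lowest ratios in their lists, Mb at -3.74 and Car6 at -3.45, also lay below the neuron range. The bound of Nnat lay below both, but no test was set for these tissues, so their content stays open for Nnat. For Rasgrf1 and Blcap, tissue content and imprinting cannot be told apart, since Blcap at 1.27 lay within that range and Rasgrf1 has only a lower bound, 1.78, just under its top. Probe sets at least 2-fold apart in both directions were rare, in 4 of 5130 genes, or 0.0780%, the others being Asph, Crat and Mfsd4a. That share lay under the bar set beforehand for noise, but so few genes passed 2-fold either way that the bar could hardly be reached. Noise between the H13 probe sets therefore stays open, and the opposite direction rests on 1455631_at alone, with signals of 96.1 and 401. A candidate explanation, not tested here, is that the H13 probe sets read different transcripts with opposite parental origin.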
